A study of Homo sapiens with 12 samples.

How the data were processed

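The series holds 12 RNA-seq libraries of H9 FUCCI cells, 2 for each of 6 groups formed by treatment (control or 2% DMSO) and sorted phase (early G1, late G1, S/G2/M). Per the labels, cells were plated with 10 micromolar Y-27632, were cultured with or without DMSO for 24 h after a first 24 h, and were then sorted on their FUCCI fluorescence. Libraries were made from total RNA with an amplifying kit and sequenced in pairs. The submitters' processing notes name Trimmomatic 0.36 for trimming, STAR 2.5.3a for alignment to GRCh38 and RSEM 1.1.17 for quantification. The deposited expected counts are RSEM's estimates of fragments per gene, made by the authors before deposit and given without rounding or scaling. The deposited TPM values were likewise made by the authors with RSEM, which divides estimated counts by effective transcript length and scales each library to the same sum. Whether counting used the strand of reads is not given in the sources used here. Other quantities in the deposit, such as transcript-level values, are not used here. Gene IDs were given symbols, lengths and coordinates from GENCODE 29, which covers 56996 of 60675 IDs. The tables held 0 samples of another series.

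Expected counts were rounded and genes of low count were removed with edgeR's filterByExpr, which left 10529 genes tested and 50146 below the filter. The tested genes held at least 99.4% of counts. Libraries were scaled by TMM. Group means were fitted for the 6 groups over all 12 libraries with robust edgeR quasi-likelihood F tests on 6 residual degrees of freedom, and p was adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Every adjusted p of a single gene in the text is from this test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. DMSO was compared with control within each phase and averaged over the 3 phases, phases were compared within each treatment, and the DMSO effect was compared between phases as an interaction. CPM values in the text are counts over TMM-scaled library size, and log2 CPM used a prior count of 2.

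Gene lists (38, of which 30 had at least 5 tested members) were written before the data were examined, as were the comparisons and the rule for named genes. List tests used camera with an inter-gene correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the lists of a comparison. A list's count of risen and fallen genes is given at the threshold over all genes and when adjusted over the list alone. Another 5 lists were written after the results of single genes had been seen, and before their own tests, and appear only in the closing section.

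Genes were named by this rule. A named gene was tested, had a mean log2 CPM of at least 2, a symbol that is not a clone name and an adjusted p under 0.05, and both libraries of 1 group lay above both of the other. The 8 largest rises and 8 largest falls were eligible in each phase, 6 and 6 in the averaged comparison, 5 and 5 between control phases and 4 and 4 for interactions. The text gives those whose call held with any library left out, except where it says otherwise. Up to 4 called members per list were described, largest first, and core pluripotency, lineage, cell cycle and phosphoinositide 3-kinase genes were always reported. The results of 5 genes that the rule covers are not reported here, and their calls are left out of the comparison of alternatives.

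Library totals ran from 1361008 to 28839004 with a median of 3343648, most of it mitochondrial (59.0 to 77.7%). Within pairs of the same group, Pearson's r of log2 CPM ran from 0.871 to 0.936, and chi-square per degree of freedom from 4.67 to 26.4 over genes with at least 20 counts, so pairs differed by more than counting error. Wilson intervals and the floor of 3 counts for a group at 0 cover counting error only, since amplified reads without molecular identifiers can repeat. The analysis was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, drawn from genes with a mean of at least 20 counts. Genes were simulated independently, without the shifts in ribosomal RNA share that the libraries showed, so the false calls do not cover such shifts. The analysis recovered 15 and 81% in early G1, 13 and 66% in late G1, 22 and 80% in S/G2/M, 69 and 99% in the averaged comparison and 18 and 78% between control S/G2/M and late G1. There were 3 to 9 false calls among 9994 to 10155 genes. A simulated trend with GC content gave 1292 false calls in the averaged comparison without offsets and 0 with them.

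Alternatives set before the data were examined were DESeq2, RLE scaling, limma-voom, no low-count filter, a filter of 50 counts, log2 TPM with a pseudocount of 1 or 0.1 for genes with a mean TPM of at least 1, TPM of all genes, removal of mitochondrial and structural RNAs, a block on replicate number, fits of the compared groups alone, an adjusted p under 0.01, an absolute log2 fold change of at least 1, leaving out each library in turn, and, for the averaged comparison, the 2 libraries of each group summed with an additive model of phase and treatment. Chosen after seeing the data were offsets for GC content and length, thinning control late G1 replicate 1 to 3343635 counts, leaving out the 3 libraries above 55% MT-RNR2, leaving out the shallower library of each late G1 group, and the MT-RNR2 share as a covariate. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.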

Results

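RNA was profiled in H9 FUCCI cells, a human embryonic stem cell line that carries fluorescent reporters of cell cycle position, cultured with or without 2% DMSO for 24 h. The series addresses how a short exposure to DMSO, which is used to prime pluripotent cells for differentiation, acts at different points of the cell cycle. Cells were sorted into early G1, late G1 and S/G2/M, which gave 6 groups of 2 libraries each. A source label calls the cells induced pluripotent, whereas H9 is an embryonic line. The series text describes the 2 libraries of a group as technical replicates, so each p below measures the spread between such libraries and not between cultures.

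Total expected counts were 3107166 and 3725433 in control early G1, 28839004 and 1507545 in control late G1, and 3382982 and 3656198 in control S/G2/M (replicates 1 and 2). They were 3597996 and 3304314 in DMSO early G1, 1361008 and 2394074 in DMSO late G1, and 3411557 and 3070796 in DMSO S/G2/M. Ribosomal RNA dominated every library: MT-RNR2, the large ribosomal RNA of mitochondria, held between 42.3 and 62.7% of counts. Its group mean was 45.7, 45.2 and 48.0% in control early G1, late G1 and S/G2/M, and 47.8, 60.7 and 56.1% in the matching DMSO groups. Copies of nuclear ribosomal RNA went the other way, with group means of 8.15, 13.4 and 8.66% in control and 4.24, 1.88 and 2.92% in DMSO. No bound of the Wilson 95% interval of these shares lay more than 0.0812 percentage points from its library's value, which covers counting error only. Nuclear genes other than ribosomal RNA received between 286418 and 7227085 counts per library, with a median of 882940. Between 12873 and 20030 genes had a count. Log2 fold changes are given with their standard error, and expression in CPM as mean ± SD with n = 2.

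**Figure D1:**
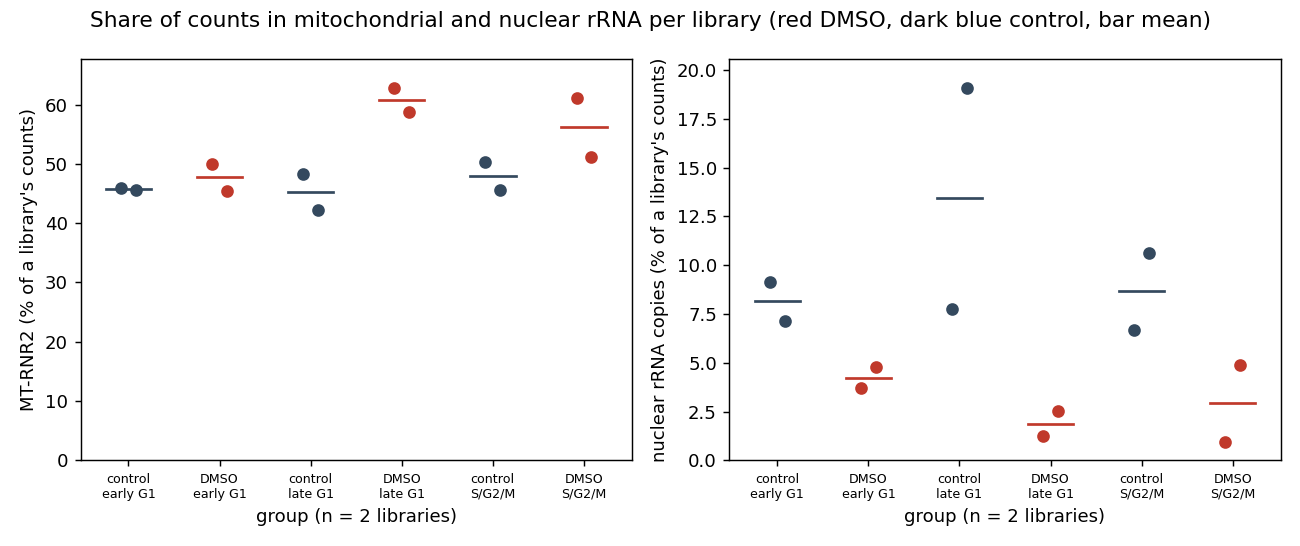
Share of expected counts (percent) held by MT-RNR2 and by copies of nuclear ribosomal RNA in each of the 12 libraries, as points by group, with the bar at the group mean. The 3 libraries above 55% MT-RNR2 are all DMSO libraries of late G1 or S/G2/M, and the DMSO libraries hold at most 4.91% nuclear ribosomal RNA against at least 6.67% in control.

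Averaged over the 3 phases, cells exposed to DMSO carried more transcript of many pluripotency genes and less of PINK1, the kinase that marks damaged mitochondria for removal. PINK1 fell by 3.96 ± 0.30 on the log2 scale (adjusted p = 3.53e-10), and PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, fell by 2.20 ± 0.20 (adjusted p = 8.15e-09). ESRG, a transcript typical of human pluripotent cells, rose by 2.29 ± 0.14 (adjusted p = 6.01e-12). LDHA, the enzyme that turns pyruvate into lactate, rose by 1.43 ± 0.10 (adjusted p = 5.93e-11). Among genes with a mean log2 CPM of at least 2 whose libraries separated in every phase, clone and LINC symbols left out, the largest rises were in JAKMIP2-AS1 (4.86 ± 0.30), APELA (3.77 ± 0.24), LRRK1 (3.34 ± 0.32), ANXA1 (3.12 ± 0.22), ERVMER34-1 (2.99 ± 0.32) and HHLA1 (2.85 ± 0.28). APELA encodes a peptide ligand of the apelin receptor, and ERVMER34-1 derives from an endogenous retrovirus. Within the same limits the largest falls after PINK1 were in JAKMIP2 (-2.75 ± 0.35), the microtubule protein gene MAP1A (-2.61 ± 0.28), the small GTPase gene RHOC (-2.50 ± 0.25) and CCDC28B (-2.49 ± 0.38). For each of them both DMSO libraries lay on the same side of both control libraries in all 3 phases. JAKMIP2-AS1 (chromosome 5, 147559994 to 147662009, plus strand, GRCh38) overlaps JAKMIP2 (147585439 to 147782848, minus strand). The use of strand in counting is not given in the sources used here, so reads of that pair cannot be told apart. The same holds for PINK1 (chromosome 1, 20633455 to 20651511) and PINK1-AS, which was looked up after its values were seen and fell by 0.86 (adjusted p = 0.000766). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1266 genes were higher and 1035 lower among 10529 tested. With TPM of all genes in place of counts, 382 were higher and 187 lower, and with the MT-RNR2 share as a covariate 336 were higher and 157 lower.

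Of 15 tested genes that mark the pluripotent state, 11 rose on average (12 when adjusted over the list alone) and 4 did not pass. Beside ESRG, the largest rises were in PRDM14 (1.74 ± 0.18), a repressor that guards the pluripotent state, TDGF1 (1.36 ± 0.11), the NODAL co-receptor also called Cripto, and PODXL (1.30 ± 0.11), a surface sialomucin. The list had a median log2 fold change of 0.64 and a camera adjusted p of 1.66e-06, with an adjusted p = 0.138 with an estimated correlation. The always reported core factors moved less evenly. NANOG rose by 1.26 ± 0.19 (adjusted p = 2e-05) and LIN28A by 0.55 ± 0.11 (adjusted p = 0.000769). POU5F1 stood at 0.01 ± 0.16 (adjusted p = 0.972), SOX2 at 0.22 ± 0.19 (adjusted p = 0.45) and the DNA methyltransferase DNMT3B at 0.37 ± 0.13 (adjusted p = 0.0521). Of 9 genes typical of primed rather than naive pluripotency, 6 rose and 1 fell (6 and 1 when adjusted over the list alone), with rises in ZIC2 (2.47 ± 0.38), OTX2 (2.29 ± 0.34), ZIC5 (1.57 ± 0.34) and CD24 (1.24 ± 0.11). Their median was 0.83 (camera adjusted p = 0.00866, and adjusted p = 0.138 with an estimated correlation), and 0.52 with no call (0.402) under a stricter filter. Only 3 of 14 genes of the naive state were expressed highly enough to be tested, with a median of -1.04.

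Most markers of lineage commitment were below the expression filter. SOX17, the endoderm regulator, had 0 counts in all 12 libraries, which allows at most 0.0485 CPM over the series, while EOMES had 78, TBXT 9 and PAX6 12 counts over the 12 libraries. Only 2 of 17 mesendoderm and endoderm markers, 2 of 18 mesoderm markers, 6 of 20 neural and 3 of 10 neural crest markers passed the expression filter. So did 1 of 13 endothelial and blood markers, 1 of 17 trophoblast and amnion markers and 0 of 31 HOX genes. Among these, CER1, a secreted antagonist of NODAL and BMP, rose by 2.76 ± 0.49 (adjusted p = 0.000176) and KDR, a receptor of vascular endothelial growth factor, by 2.02 ± 0.19 (adjusted p = 9.52e-09). SOX3 rose by 1.52 ± 0.41 and ETS1 by 1.47 ± 0.26, whereas TUBB3 fell by 0.99 ± 0.19 and SOX9 by 2.01 ± 0.48. Of 5 tested fibroblast and mesenchymal markers 3 rose and 1 fell (3 and 1 when adjusted over the list alone), with VIM at 1.60 ± 0.12, TAGLN at 1.01 ± 0.23, COL1A1 at 0.73 ± 0.15 and FBN1 at -1.61 ± 0.38. That list did not pass (camera adjusted p = 0.0765). Of 13 epithelial adhesion genes 5 fell (6 when adjusted over the list alone). They included the claudins CLDN4 (-2.56 ± 0.53) and CLDN3 (-2.48 ± 0.53), which seal tight junctions, and JUP (-1.62 ± 0.24), a desmosomal catenin. The epithelial list passed with a camera adjusted p of 0.0485 and lost its call with an adjusted p = 0.281 with an estimated correlation. It was also lost without control early G1 replicate 1 (0.0597), control late G1 replicate 1 (0.0715), control S/G2/M replicate 1 (0.06), DMSO early G1 replicate 2 (0.0502), DMSO late G1 replicate 2 (0.128) or DMSO S/G2/M replicate 2 (0.1), under a stricter filter (median -0.22, 0.253) and with GC and length offsets (-0.23, 0.0757).

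Among signalling genes, the antagonist LEFTY2 rose by 2.36 ± 0.21 (adjusted p = 6.59e-09) while its agonist NODAL fell by 2.20 ± 0.40 (adjusted p = 0.000207). LEFTY1 stood at -0.19 ± 0.17 (adjusted p = 0.476). Of 20 tested genes of the activin, NODAL and TGF-beta pathway 6 rose and 2 fell (8 and 2 when adjusted over the list alone), with INHBE at 2.44 ± 0.45. For 33 genes of phosphoinositide 3-kinase and AKT signalling 5 rose and 5 fell (5 and 5 when adjusted over the list alone). FOXO1, a transcription factor that AKT keeps out of the nucleus, rose by 1.87 ± 0.23 (adjusted p = 1.3e-06) and the AKT phosphatase gene PHLPP1 by 1.00 ± 0.17 (adjusted p = 0.000131). PIK3CA (0.54 ± 0.38) did not pass. AKT1 was at the threshold (-0.85 ± 0.31, adjusted p = 0.0493), and its call held only without control late G1 replicate 1 or DMSO S/G2/M replicate 2, with 0.0512 to 0.173 when another library was left out. PIK3R1 fell by 1.01 ± 0.30 (adjusted p = 0.0161), a call lost without control early G1 replicate 1, control late G1 replicate 1, control S/G2/M replicate 2 or DMSO late G1 replicate 1 (0.089, 0.0906, 0.0629 and 0.052). FGF2, the growth factor that sustains pluripotent cultures, rose by 1.72 ± 0.32, and DUSP6, a phosphatase induced by ERK activity, fell by 0.96 ± 0.16. Their pathway list of 19 genes had 4 rises and 2 falls (6 and 2 when adjusted over the list alone). In the WNT list of 22 genes 4 rose and 4 fell (5 and 4 when adjusted over the list alone). They included WNT3 at -1.96 ± 0.34, the receptor gene FZD5 at 1.62 ± 0.31 and the target gene SP5 lower (adjusted p = 0.000127). The BMP list of 9 genes had 2 rises (2 when adjusted over the list alone), among them BAMBI at 1.33 ± 0.29. In addition 3 of 8 YAP targets rose (3 when adjusted over the list alone), among them AXL at 1.34 ± 0.26. None of the 6 tested NOTCH genes or 6 Hedgehog genes passed. Of 10 tested immediate early genes 4 fell (4 when adjusted over the list alone), including EGR1 (-1.88 ± 0.24), IER2 (-0.93 ± 0.21) and BTG2 (adjusted p = 1.12e-06). The camera adjusted p was 0.157 for the activin list, 0.823 for the phosphoinositide 3-kinase list, 0.233 for the ERK list, 0.69 for the WNT list and 0.102 for the immediate early list.

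Metabolic and stress genes moved in both directions. PDK1, which holds pyruvate back from mitochondria, rose by 2.07 ± 0.20 (adjusted p = 2.12e-08), while the glucose transporter gene SLC2A1 fell by 1.24 ± 0.11 (adjusted p = 7.67e-09). Of 18 glycolysis and hypoxia genes 6 rose and 3 fell (8 and 3 when adjusted over the list alone, camera adjusted p = 0.233). PSAT1 of serine synthesis (1.01 ± 0.14), the transcription factor gene ATF4 (0.71 ± 0.13) and the cystine transporter gene SLC7A11 (1.53 ± 0.30) were among 5 of 19 stress response genes that rose (7 rises and 1 fall when adjusted over the list alone, camera adjusted p = 0.247). Of 24 cholesterol synthesis genes 1 rose and 5 fell (1 and 5 when adjusted over the list alone), among them MVD (-1.52 ± 0.21). NQO1 (-0.87 ± 0.16) and FTL (-0.67 ± 0.12) fell in the NRF2 list of 13, with 3 falls and 1 rise (3 and 1 when adjusted over the list alone). The p53 list of 14 had 1 rise and 5 falls (1 and 6 when adjusted over the list alone), among them XPC (-0.97 ± 0.20). Of 8 apoptosis genes 2 rose and 1 fell (2 and 1 when adjusted over the list alone), with the proapoptotic BMF at -1.84 ± 0.22 and PMAIP1 at 0.96 ± 0.18. Of 13 heat shock genes 3 rose and 3 fell (3 and 3 when adjusted over the list alone), with HSPD1 at 0.77 ± 0.10 and DNAJB1 at -1.06 ± 0.23. Matrix and basement membrane genes numbered 4 rises among 17 (5 when adjusted over the list alone), among them ITGAV (1.04 ± 0.24), FN1 (0.75 ± 0.17) and ITGB1 (0.73 ± 0.16). Ribosomal protein genes were split, with 12 rises and 14 falls among 75 (13 and 14 when adjusted over the list alone). RPL9 rose by 0.75 ± 0.11 and RPL18 fell by 0.60 ± 0.15, a gene whose sign turned (0.074) with the MT-RNR2 share as a covariate. HDAC2, a histone deacetylase gene, rose by 0.86 ± 0.20 in a chromatin list of 20 with 2 rises and 3 falls (3 and 3 when adjusted over the list alone). RN7SK, the RNA that restrains the elongation factor P-TEFb, fell by 0.85 ± 0.10 (adjusted p = 2.07e-07), a fall absent in early G1 (-0.01 ± 0.16, adjusted p = 0.977). The 3 tested metallothionein genes and the 13 members of the mitochondrially encoded list held no call in the averaged comparison by edgeR. In it 10529 genes were tested and 3646 had an unadjusted p under 0.05. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 are outside that list and were both called, MT-RNR2 at 0.29 (adjusted p = 0.0307). MT-RNR1 went the other way in its share of counts in the later phases. It held 10.9 and 11.7% in DMSO late G1 against 16.0 and 14.5% in control, and 10.4 and 12.4% against 15.3 and 15.4% in S/G2/M. In early G1 it held 14.2 and 14.4% with DMSO against 14.4 and 14.5% in control.

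Cell cycle genes did not move as 1 block. Of 42 S phase genes 11 rose and 1 fell (13 and 2 when adjusted over the list alone), led by the helicase gene HELLS (2.31 ± 0.24, adjusted p = 7.66e-08), with TIPIN at 1.13 ± 0.25. The list passed with a median of 0.31 and a camera adjusted p of 0.0281 (adjusted p = 0.138 with an estimated correlation). That call was lost with the MT-RNR2 share as a covariate (0.12, 0.122), with GC and length offsets (0.25, 0.0757) and with a stricter filter (0.38, 0.253). The median was 0.19 without DMSO late G1 replicate 2. It was 0.083 without the 3 libraries of highest MT-RNR2 share. That fit holds no DMSO library of late G1, so its average covers early G1 and S/G2/M only. The G2 and mitosis list of 54 had 6 rises and 6 falls (7 and 6 when adjusted over the list alone, camera adjusted p = 0.823), among them TMPO (1.32 ± 0.24) and CKS2 (-0.91 ± 0.19). Of 34 cyclins, kinases and inhibitors 3 rose and 3 fell (3 and 3 when adjusted over the list alone, camera adjusted p = 0.733). WEE1, which holds cells before mitosis, rose by 1.17 ± 0.17 and CCND2 by 0.54 ± 0.11 (adjusted p = 0.0011), while CCND3 fell by 1.43 ± 0.32 (adjusted p = 0.00167), the inhibitor gene CDKN2D by 2.26 ± 0.44 and CDC25B by 0.89 ± 0.22. No call was made for CCND1 (0.11 ± 0.15), CCNE1 (-0.13 ± 0.22), CCNA2 (0.23 ± 0.14), CCNB1 (0.01 ± 0.14), MKI67 (-0.01 ± 0.18), RB1 (-0.05 ± 0.29), RBL1 (0.24 ± 0.32), RBL2 (-0.44 ± 0.32), CDKN1B (-0.32 ± 0.37) or MYC (0.38 ± 0.19). TOP2A stood at 0.02 ± 0.16, and at -0.47 over early G1 and S/G2/M without the 3 libraries of highest MT-RNR2 share. CDT1 (-0.24 ± 0.27) and GMNN (0.16 ± 0.25) did not pass either, and their counts can include fragments of the FUCCI reporters built from these genes. CDKN1A and CDKN1C, with 108 and 36 counts over the 12 libraries, fell below the filter and were not tested. In early G1, late G1 and S/G2/M, mean CPM of CDKN1A was 2.13, 0.99 and 4.02 in control. With DMSO it was 0, 0.93 and 0.60. For CDKN1C these were 0.90, 1.06 and 0.53 in control and 0.38, 0.70 and 0.30 with DMSO. Of 46 replication-dependent histone genes, whose near-identical copies share reads, 12 fell (12 when adjusted over the list alone), among them HIST1H2BC (-0.95 ± 0.14) and HIST2H4B (-1.14 ± 0.24). The histone median was -0.42 (camera adjusted p = 0.00012, and adjusted p = 0.511 with an estimated correlation). It was -0.04 over early G1 and S/G2/M without the 3 libraries of highest MT-RNR2 share, an average that leaves out late G1. Over the 3 phases it was 0.23 with the MT-RNR2 share as a covariate.

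**Figure D2:**
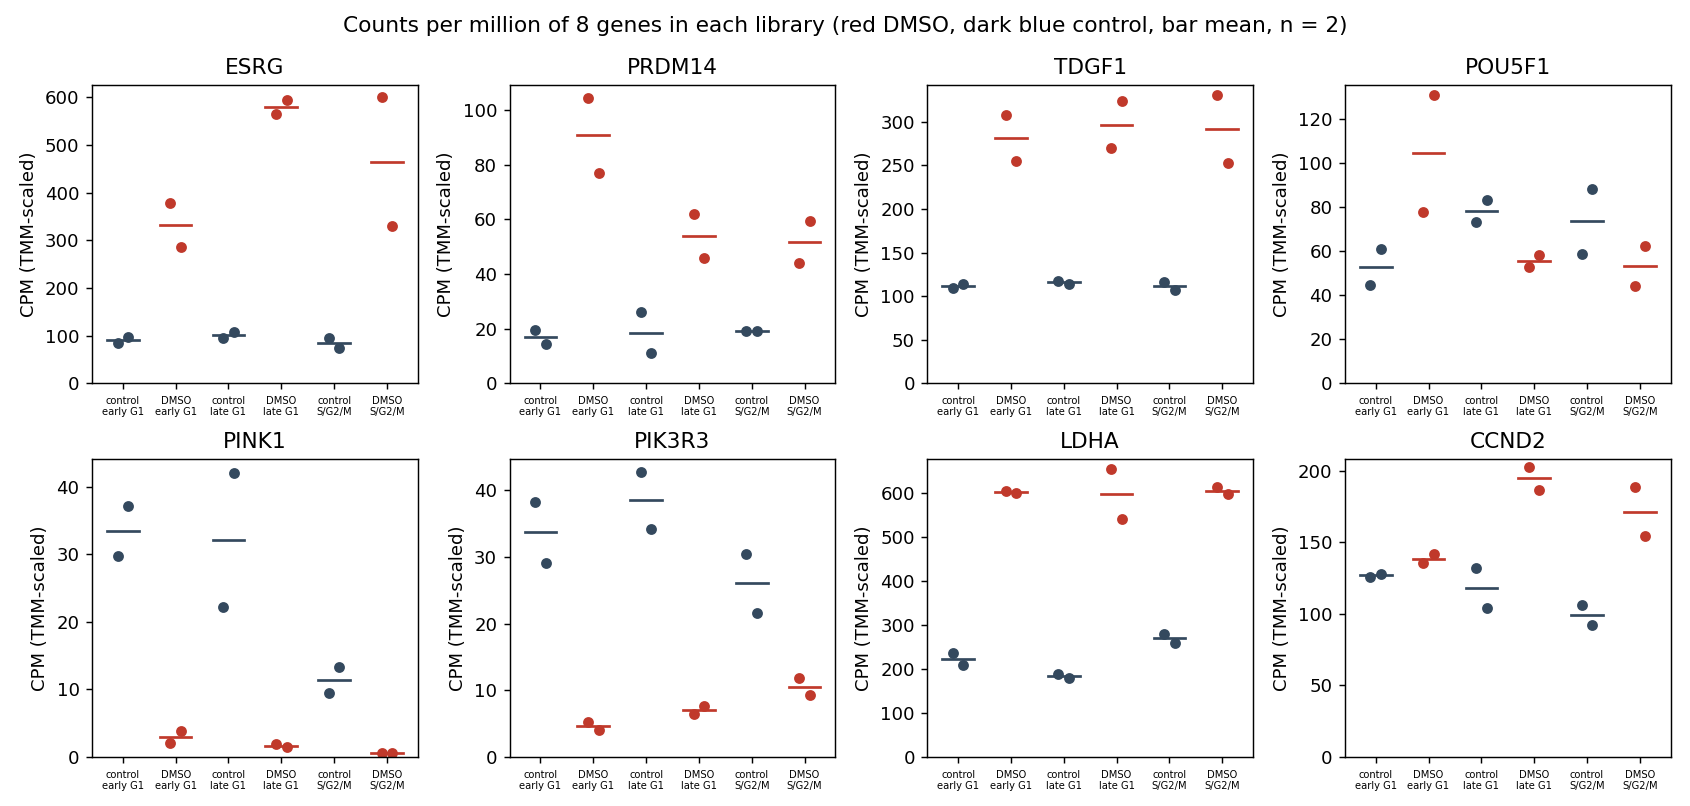
CPM per library (linear scale) of ESRG, PRDM14, TDGF1, POU5F1, PINK1, PIK3R3, LDHA and CCND2 in early G1, late G1 and S/G2/M, with DMSO in red, control in dark blue and bars at the mean of n = 2. ESRG and LDHA lie higher and PINK1 lower in both DMSO libraries than in both control libraries of every phase, whereas POU5F1 does not separate on average (log2 fold change 0.01).

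In early G1, where the libraries of the compared groups were most alike in composition, several pluripotency genes were higher with DMSO. ESRG rose from 90.6 ± 10.2 to 332 ± 65.8 CPM (n = 2, log2 fold change 1.87 ± 0.23), PRDM14 from 16.9 ± 3.63 to 90.7 ± 19.5 CPM (2.43 ± 0.31) and TDGF1 from 112 ± 3.19 to 282 ± 37.3 CPM (1.33 ± 0.20). PINK1 fell from 33.4 ± 5.16 to 2.93 ± 1.18 CPM (-3.50 ± 0.42, adjusted p = 1.32e-05) and PIK3R3 from 33.7 ± 6.51 to 4.63 ± 0.871 CPM (-2.86 ± 0.35, adjusted p = 1.32e-05). LDHA rose from 223 ± 20.3 to 602 ± 3.46 CPM (1.44 ± 0.18). The largest rises that held with any library left out were JAKMIP2-AS1 (5.90 ± 0.57), LRRK1 (3.16 ± 0.56), APELA (3.08 ± 0.40), FGFBP3 (3.05 ± 0.31), which encodes a carrier of fibroblast growth factors, and ANXA1 (2.78 ± 0.37). The largest such falls were MAP1A (-3.65 ± 0.50), PINK1, JAKMIP2 (-3.48 ± 0.62), WNT3 (-3.21 ± 0.58) and PIK3R3. LEFTY2 (2.15 ± 0.35), KDR (2.31 ± 0.33), PDK1 (2.20 ± 0.35), OTX2 (3.48 ± 0.60), CD24 (1.29 ± 0.20) and VIM (1.85 ± 0.21) rose, while SLC2A1 (-1.18 ± 0.19) and EGR1 (-2.33 ± 0.40) fell. SP5 had 0 counts in both DMSO libraries, at least 7.96-fold lower than control against a floor of 3 counts over the group. Its call (adjusted p = 0.0178) was lost without control early G1 replicate 1 (0.0733) or 2 (0.0921) and without DMSO early G1 replicate 1 (0.155) or 2 (0.159). POU5F1 was at 104 ± 37.7 against 52.7 ± 11.6 CPM (0.98 ± 0.27, adjusted p = 0.0355), and lost its call without control early G1 replicate 1 (0.37) or 2 (0.0986) or DMSO early G1 replicate 2 (0.548). NANOG (0.95 ± 0.32, adjusted p = 0.105), SOX2 (0.01 ± 0.32), CCND1 (-0.08 ± 0.25), CCND2 (0.13 ± 0.20), CCNA2 (0.36 ± 0.24) and MKI67 (-0.45 ± 0.31) did not pass.

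As groups in early G1, 7 of 15 pluripotency genes rose (10 when adjusted over the list alone), with a median of 0.92 and a camera adjusted p of 3.09e-06 (adjusted p = 0.132 with an estimated correlation). Of 9 primed pluripotency genes 3 rose (6 rises and 1 fall when adjusted over the list alone, median 0.71, camera adjusted p = 0.00583, adjusted p = 0.132 with an estimated correlation). Under a stricter filter that median was 0.32 (0.482). Of 42 S phase genes 3 rose (5 when adjusted over the list alone, median 0.43, camera adjusted p = 0.0102, adjusted p = 0.132 with an estimated correlation), and the stricter filter gave 0.26 (0.135). Of 13 epithelial adhesion genes 1 fell (6 when adjusted over the list alone, median -0.54, camera adjusted p = 0.00847, adjusted p = 0.159 with an estimated correlation), with -0.43 (0.0537) under that filter. Among 5 fibroblast markers VIM rose (3 when adjusted over the list alone, camera adjusted p = 0.0395, adjusted p = 0.167 with an estimated correlation), a call lost without DMSO late G1 replicate 1 (0.0793) or 2 (0.0785). Of 10 immediate early genes 2 fell (3 when adjusted over the list alone, camera adjusted p = 0.0412, adjusted p = 0.167 with an estimated correlation), a call lost without control early G1 replicate 1 (0.128). Histone genes had a median of 0.29 and did not pass (camera adjusted p = 0.233). In all, 237 genes were higher and 122 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, against 20 and 1 with TPM and a pseudocount of 1 and 13 and 1 with a pseudocount of 0.1. The total of 359 became 117 and 137 without control early G1 replicates 1 and 2, 130 and 150 without DMSO early G1 replicates 1 and 2, and 688 without either DMSO S/G2/M library.

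In late G1, the same pluripotency transcripts and LDHA were higher with DMSO, and PINK1 and EGR1 were lower. ESRG rose from 101 ± 9.83 to 580 ± 21.0 CPM (n = 2, 2.53 ± 0.24, adjusted p = 5.25e-07) and LDHA from 184 ± 7.49 to 597 ± 80.0 CPM (1.70 ± 0.18, adjusted p = 9.39e-07). APELA rose from 5.19 ± 1.84 to 118 ± 8.73 CPM (4.31 ± 0.42), and PINK1 fell from 32.1 ± 14.1 to 1.65 ± 0.291 CPM (-4.23 ± 0.56). STRADA, a pseudokinase that activates the tumour suppressor LKB1, fell from 12.3 ± 3.05 to 0.240 ± 0.340 CPM (-5.25 ± 0.87, adjusted p = 0.000453). It overlaps LIMD2 on the same strand of chromosome 17, which was looked up after its values were seen and also fell (adjusted p = 0.0453). JAKMIP2-AS1 (4.60 ± 0.48), ANXA1 (3.74 ± 0.39), LRRK1 (3.43 ± 0.53), the coagulation inhibitor gene TFPI (3.15 ± 0.56) and HHLA1 (2.92 ± 0.49) were the other large rises that held with any library left out. PIK3R3 fell by 2.44 ± 0.38, a call that held likewise. LIN28B (1.39 ± 0.25), TDGF1 (1.36 ± 0.20), CD24 (1.26 ± 0.20), LEFTY2 (2.33 ± 0.38), PDK1 (2.25 ± 0.36) and PSAT1 (1.46 ± 0.25) rose. SLC2A1 (-1.25 ± 0.20), EGR1 (-2.46 ± 0.45), RN7SK (-1.28 ± 0.17) and HIST1H2BC (-1.42 ± 0.26) fell. NANOG was at 48.1 ± 2.58 CPM with DMSO against 20.4 ± 1.29 in control, and CCND2 at 195 ± 11.6 against 118 ± 19.3 CPM. POU5F1 (-0.48 ± 0.28, adjusted p = 0.322), SOX2 (0.15 ± 0.34), CCND1 (-0.03 ± 0.26), CCNB1 (0.50 ± 0.24), MKI67 (0.50 ± 0.32) and TOP2A (0.52 ± 0.29) did not pass.

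Of the gene groups in late G1, 7 of 15 pluripotency genes rose (10 when adjusted over the list alone, median 0.84, camera adjusted p = 0.000794, adjusted p = 0.385 with an estimated correlation). With the MT-RNR2 share as a covariate that median was 0.54 and the call was lost (0.0708). Of 9 primed pluripotency genes 3 rose and 1 fell (6 and 1 when adjusted over the list alone, median 0.84, camera adjusted p = 0.0363, adjusted p = 0.385 with an estimated correlation), a call lost without control late G1 replicate 1 (0.109) or DMSO late G1 replicate 2 (0.132), with a stricter filter (0.57, 0.69) and with that covariate (0.90, 0.0708). Of 42 S phase genes 3 rose (3 when adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.00169, adjusted p = 0.128 with an estimated correlation), which became 0.21 (0.0708) with the covariate and 0.39 (0.143) with a stricter filter. Of 46 histone genes 6 fell (6 when adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.04e-06, adjusted p = 0.501 with an estimated correlation), which became 0.20 (0.384) with the MT-RNR2 share as a covariate and -1.02 without control late G1 replicate 1. The 13 genes encoded by mitochondrial DNA had a median of 0.82 (camera adjusted p = 0.00804, adjusted p = 0.626 with an estimated correlation), lost without DMSO late G1 replicate 1 (0.51, 0.102), with GC and length offsets (0.50, 0.229) and without the shallowest late G1 libraries (0.35, 0.182), and turned to -0.63 with that covariate. G2 and mitosis genes numbered 4 rises and 2 falls of 54 (8 and 4 when adjusted over the list alone, camera adjusted p = 0.145). By edgeR 446 genes were higher and 273 lower, against 557 and 122 with limma-voom, 345 and 396 with no expression filter, 24 and 7 with TPM of all genes, and 25 and 6 with the MT-RNR2 share as a covariate. The total of 719 became 296 and 244 without control late G1 replicates 1 and 2, 257 and 223 without DMSO late G1 replicates 1 and 2, and 1176 and 1200 without DMSO S/G2/M replicates 1 and 2. Without the shallower library of each late G1 group it was 97 (79 higher, 18 lower).

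In S/G2/M, pluripotency transcripts and the NODAL antagonist LEFTY2 were higher with DMSO and PINK1 was lower. ESRG rose from 84.4 ± 14.4 to 465 ± 190 CPM (n = 2, 2.46 ± 0.24, adjusted p = 7.68e-07), PODXL by 1.52 ± 0.19 (adjusted p = 2.05e-05), TDGF1 by 1.38 ± 0.20 (adjusted p = 7.89e-05) and LEFTY2 by 2.62 ± 0.38 (adjusted p = 8.79e-05). PINK1 fell from 11.4 ± 2.75 to 0.616 ± 0.0299 CPM (-4.16 ± 0.60, adjusted p = 8.39e-05), together with the cyclophilin gene PPIC (-2.75 ± 0.51), the centrosome gene ODF2 (-2.69 ± 0.47) and RHOC (-2.52 ± 0.43). JAKMIP2-AS1 (4.08 ± 0.48), APELA (3.91 ± 0.43), ERVMER34-1 (3.75 ± 0.56), LRRK1 (3.45 ± 0.57) and PCBP1-AS1 (3.13 ± 0.49), which overlaps the PCBP1 locus on the other strand, were the largest rises that held with any library left out. KDR (2.16 ± 0.32), VIM (1.54 ± 0.21), CD24 (1.18 ± 0.20), LDHA (1.17 ± 0.17) and HELLS (2.22 ± 0.41) rose, and SLC2A1 (-1.28 ± 0.19) and RN7SK (-1.26 ± 0.17) fell. NANOG was at 44.5 ± 26.3 CPM with DMSO against 14.5 ± 0.243 in control, and CCND2 at 171 ± 24.2 against 99.1 ± 9.54 CPM. POU5F1 (-0.47 ± 0.27, adjusted p = 0.375), CCNB1 (-0.62 ± 0.23, adjusted p = 0.146), TOP2A (-0.32 ± 0.26), MKI67 (-0.10 ± 0.30) and CCNA2 (-0.34 ± 0.24) did not pass.

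As groups in S/G2/M, 9 of 15 pluripotency genes rose (10 when adjusted over the list alone, median 1.02, camera adjusted p = 4.78e-07, adjusted p = 0.112 with an estimated correlation). In the activin, NODAL and TGF-beta pathway 4 of 20 genes rose (8 rises and 1 fall when adjusted over the list alone, median 0.48, camera adjusted p = 0.00267, adjusted p = 0.112 with an estimated correlation). Of 54 G2 and mitosis genes 1 rose and 4 fell (2 and 6 when adjusted over the list alone, median -0.40, camera adjusted p = 0.00114, adjusted p = 0.125 with an estimated correlation), a call lost without DMSO S/G2/M replicate 2 (0.139). Of 46 histone genes 6 fell (9 when adjusted over the list alone, median -0.74, camera adjusted p = 3.98e-08, adjusted p = 0.315 with an estimated correlation), which became -0.29 (0.0552) without DMSO S/G2/M replicate 1, -1.22 without DMSO S/G2/M replicate 2, -0.48 without control S/G2/M replicate 2, -0.30 (0.0621) without the 3 libraries of highest MT-RNR2 share and -0.13 (0.281) with the MT-RNR2 share as a covariate. Of 17 matrix genes 3 rose (5 when adjusted over the list alone, median 0.66, camera adjusted p = 0.00242, adjusted p = 0.112 with an estimated correlation), lost without DMSO S/G2/M replicate 2 (0.0533). Of 9 primed pluripotency genes 3 rose (4 when adjusted over the list alone, median 1.05, camera adjusted p = 0.00989, adjusted p = 0.125 with an estimated correlation), lost without control S/G2/M replicate 2 (0.0533) or DMSO S/G2/M replicate 2 (0.0533) and with a stricter filter (0.58, 0.132). S phase genes had a median of 0.01 (camera adjusted p = 0.889). YAP targets (camera adjusted p = 0.037) and fibroblast markers (0.0499) passed narrowly, with adjusted p = 0.315 and adjusted p = 0.231 with an estimated correlation. The YAP call held only without control early G1 replicate 2, control late G1 replicate 1, control S/G2/M replicate 1 or DMSO early G1 replicate 1, and the fibroblast call only without control S/G2/M replicate 1 or DMSO S/G2/M replicate 1. Otherwise their adjusted p lay between 0.0552 and 0.164 and between 0.0657 and 0.286. By edgeR 293 genes were higher and 135 lower, against 36 and 6 with TPM and a pseudocount of 1, 25 and 2 with a pseudocount of 0.1, and 196 in all with the MT-RNR2 share as a covariate. The total of 428 became 153 and 89 without control S/G2/M replicates 1 and 2, and 281 and 994 without DMSO S/G2/M replicates 1 and 2.

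Many effects of DMSO were shared by the 3 phases. JAKMIP2-AS1, APELA, LRRK1, ESRG, TDGF1, VIM and LDHA rose and PINK1 and SLC2A1 fell in each of them, among 116 genes higher and 28 lower in all 3. Of 1039 genes called in at least 1 phase, none had an opposite call in another phase by edgeR's test. Early and late G1 shared 160 higher and 55 lower genes, where independent lists would share 10.0 and 3.16. Early G1 and S/G2/M shared 132 and 34 (6.60 and 1.56 for independent lists), and late G1 and S/G2/M shared 171 and 59 (12.4 and 3.50). The phases may have been sorted from the same cultures. A difference between cultures or preparations could then recur in all 3 phases, so this sharing is not replication across cultures. Across the 10529 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.507 between early and late G1 (Spearman's rho 0.524), 0.486 between early G1 and S/G2/M (0.489) and 0.452 between late G1 and S/G2/M (0.464), with no library in common. The first r was 0.332 without control early G1 replicate 2, 0.323 without control late G1 replicate 1 and 0.312 without DMSO late G1 replicate 2. The second was 0.311 without DMSO S/G2/M replicate 1, and the last was 0.265 without DMSO late G1 replicate 2 and 0.251 without DMSO S/G2/M replicate 1. No gene differed in its DMSO effect between phases by edgeR's test, with 562 genes at an unadjusted p under 0.05 for late against early G1 (DESeq2 called 1 and limma-voom 1). There were 684 for S/G2/M against late G1 (DESeq2 1, limma-voom 0) and 502 for S/G2/M against early G1 (DESeq2 2, limma-voom 1). Chance alone gives 526. The self-test recovered 13 to 22% of 2-fold changes within a phase, so these tests can miss differences of that size. As a list, histone genes differed by camera in their DMSO effect between late and early G1, by -0.96 (camera adjusted p = 6.5e-13, adjusted p = 0.744 with an estimated correlation). That difference was -0.12 with the MT-RNR2 share as a covariate, and the call was lost with that covariate and with fry. Without DMSO S/G2/M replicate 1 the comparison of S/G2/M with late G1 called 50 genes, and without DMSO S/G2/M replicate 2 that of S/G2/M with early G1 called 16.

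**Figure D3:**
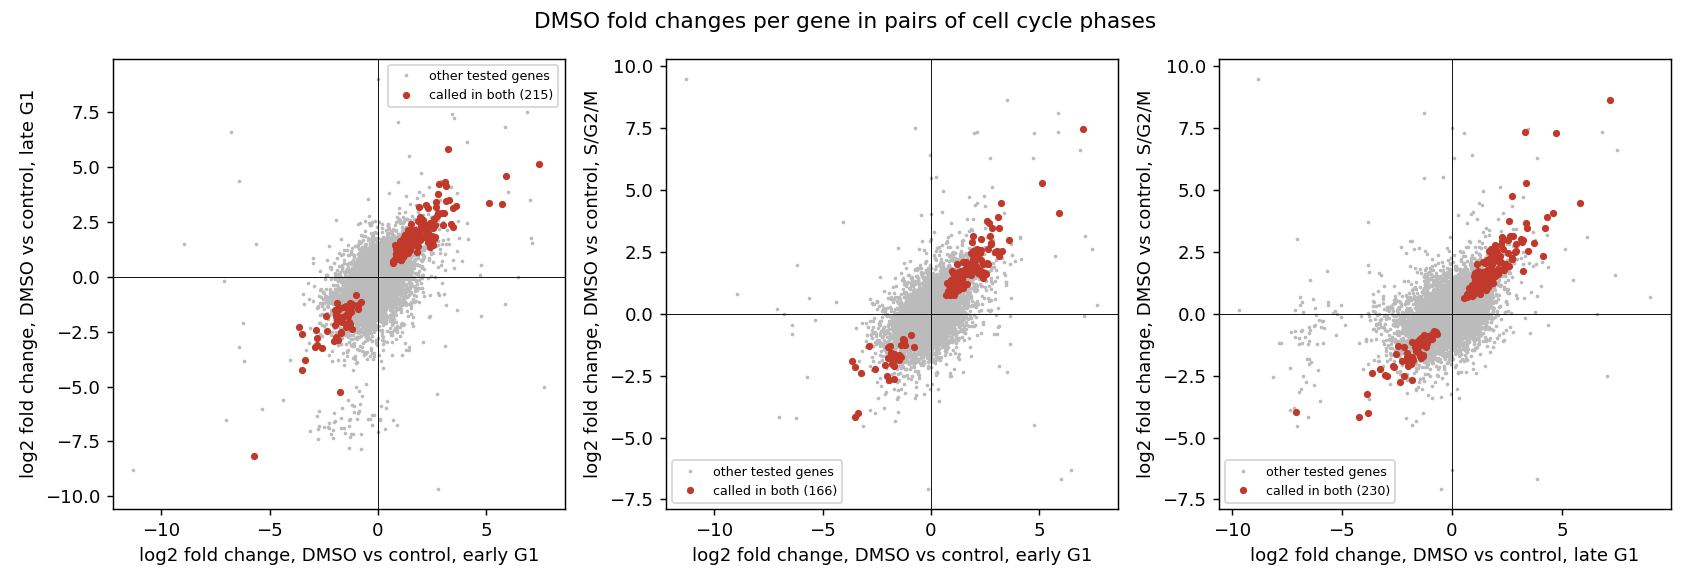
Log2 fold change of DMSO over control per gene for each pair of phases, with genes called in both phases marked (215, 166 and 230 genes). All marked genes lie in the quadrants of equal sign, and r is 0.507, 0.486 and 0.452.

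**Figure D4:**
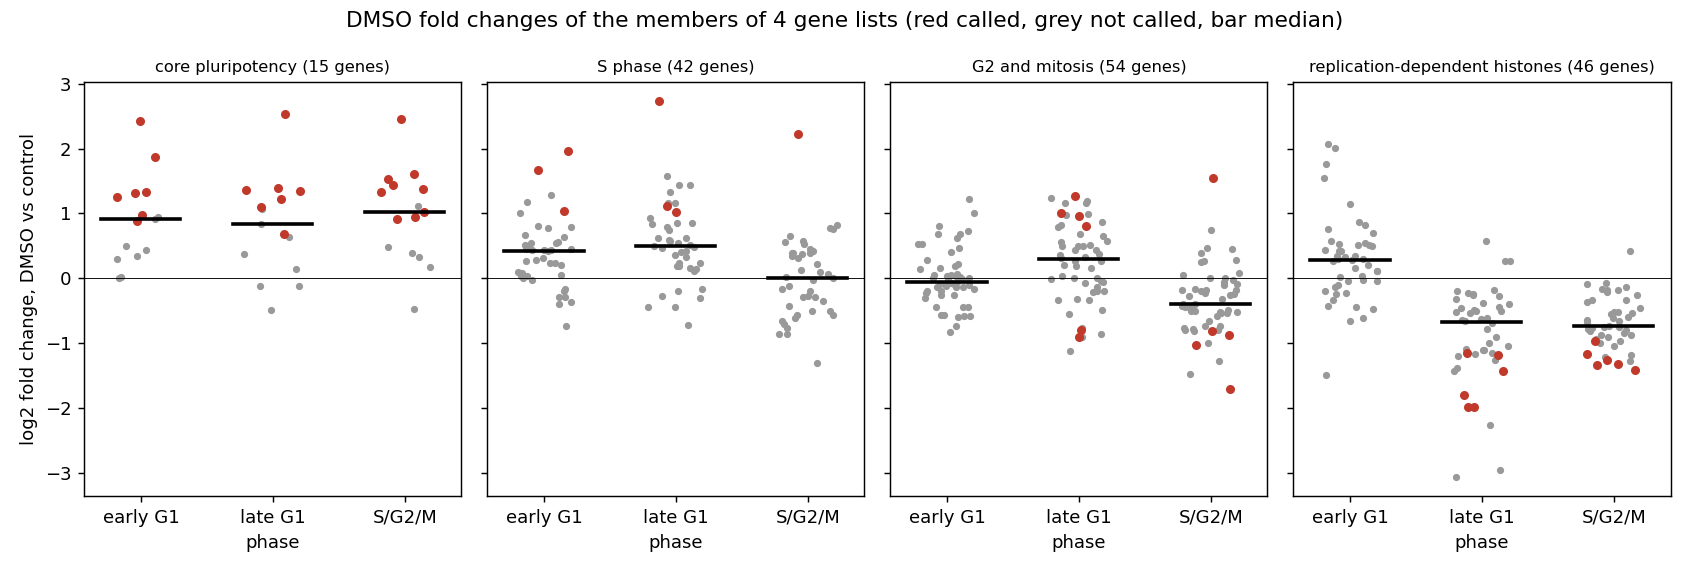
Log2 fold change of DMSO over control in early G1, late G1 and S/G2/M for each tested member of the pluripotency (15), S phase (42), G2 and mitosis (54) and histone (46) lists, with called genes in red and the bar at the median. The pluripotency median lies at 0.92, 0.84 and 1.02, while the histone median is 0.29 in early G1 and -0.67 and -0.74 in the later phases.

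Comparing phases within the control cultures checked what the sort separated. In S/G2/M against late G1, histone and mitotic genes were higher. HIST1H1D, a linker histone gene, rose from 7.95 ± 0.235 to 88.9 ± 2.29 CPM (n = 2, 3.46 ± 0.38, adjusted p = 1.07e-05). UBE2C, which targets mitotic cyclins for destruction, rose from 17.1 ± 4.41 to 79.7 ± 5.10 CPM (2.32 ± 0.27, adjusted p = 1.86e-05). TOP2A, the topoisomerase that untangles chromosomes, rose from 40.0 ± 3.78 to 138 ± 3.51 CPM (1.76 ± 0.28, adjusted p = 0.000744). HIST1H2AJ (3.07 ± 0.44) and HIST2H2BE (2.60 ± 0.36) rose as well, with the reservation about shared reads of histone copies. Of 46 histone genes 30 rose (39 when adjusted over the list alone, median 2.04, camera adjusted p = 2.97e-48, adjusted p = 0.0542 with an estimated correlation). Of 54 G2 and mitosis genes 6 rose (24 when adjusted over the list alone, median 0.72, camera adjusted p = 2.85e-15, adjusted p = 0.017 with an estimated correlation). S phase genes had a median of 0.40 (camera adjusted p = 0.00057, adjusted p = 0.046 with an estimated correlation), lost without control late G1 replicate 1 (0.0657). CCNA2 rose by 1.05 (adjusted p = 0.0496), a call lost without any library of the early or late G1 groups and without control S/G2/M replicate 2. CCNB1 (0.80 ± 0.24), MKI67 (0.79 ± 0.31), CCND1 (-0.41 ± 0.25) and CCNE1 (-0.06 ± 0.37) did not pass. By edgeR 41 genes were higher and 0 lower, with 582 at an unadjusted p under 0.05. With other settings, 57 were higher and 10 lower with no expression filter and 7 and 1 with TPM of all genes. The count was 26 without control late G1 replicate 1 (12 higher, 14 lower), 16 without control S/G2/M replicate 2, and 64 and 65 without DMSO S/G2/M replicates 1 and 2. Matrix genes passed narrowly with a median of -0.34 (camera adjusted p = 0.0271, adjusted p = 0.152 with an estimated correlation). Their call held only without control late G1 replicate 2 or DMSO early G1 replicate 1, with 0.0513 to 0.257 otherwise and a median of -0.22 without control late G1 replicate 1.

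In S/G2/M against early G1 of control cultures, HIST1H2AJ rose by 3.19 ± 0.45, HIST1H1D by 2.56 ± 0.35 and RN7SK by 1.16 ± 0.17 (each adjusted p = 0.000315). Of 46 histone genes 28 rose (41 when adjusted over the list alone, median 1.85, camera adjusted p = 1.71e-55, adjusted p = 0.058 with an estimated correlation). Of 54 G2 and mitosis genes 2 rose (9 when adjusted over the list alone, median 0.45, camera adjusted p = 1.71e-08, adjusted p = 0.058 with an estimated correlation). By edgeR 31 genes were higher and 0 lower, with 629 at an unadjusted p under 0.05, against 49 and 18 with no expression filter and 14 and 16 with TPM of all genes. Structural noncoding RNAs passed in this comparison (median 0.28, camera adjusted p = 0.0477, adjusted p = 0.374 with an estimated correlation), a call that held only without control S/G2/M replicate 1 (0.0552 to 0.892 otherwise, with a median of -0.038 without control S/G2/M replicate 2). The gene count was 19 without control S/G2/M replicate 2 and 55 and 56 without DMSO S/G2/M replicates 1 and 2. Late and early G1 of control differed in RN7SK alone, from 747 ± 42.0 to 1900.0 ± 16.5 CPM (n = 2, 1.35 ± 0.17, adjusted p = 9.82e-05), with 363 genes at an unadjusted p under 0.05 fewer than the 526 that chance gives. DESeq2 called 1 gene and limma-voom 2. That count was 8 and 14 without control early G1 replicates 1 and 2 and 12 and 3 without control late G1 replicates 1 and 2. CCND1 (0.10 ± 0.25), CCNE1 (-0.17 ± 0.37), CDT1 (0.58 ± 0.43) and CCNA2 (-0.50 ± 0.24) did not pass. Of 7 tested structural noncoding RNAs 1 rose (5 when adjusted over the list alone, camera adjusted p = 8.23e-07, adjusted p = 0.0586 with an estimated correlation). G2 and mitosis genes had a median of -0.23 (camera adjusted p = 0.00488, adjusted p = 0.231 with an estimated correlation), lost without control early G1 replicate 1 (0.115) or control late G1 replicate 1 (0.267). Ribosomal protein genes had a median of 0.18 (camera adjusted p = 0.00046, adjusted p = 0.701 with an estimated correlation), lost without control early G1 replicate 2 (0.0704) and turned to -0.17 with TPM and a pseudocount of 1 or 0.1. NOTCH genes passed here (median 0.60, camera adjusted p = 0.0138, adjusted p = 0.231 with an estimated correlation), a call that held only without DMSO S/G2/M replicate 1 or 2 (0.0559 to 0.49 otherwise, with medians of 0.94 without control early G1 replicate 2 and 0.38 without control late G1 replicate 2).

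Within the DMSO cultures, S/G2/M again stood apart from late G1 by its histone genes. HIST1H1D rose by 2.97 ± 0.43 (adjusted p = 0.000427), and 22 of 46 histone genes rose (40 when adjusted over the list alone, median 2.01, camera adjusted p = 5.29e-40, adjusted p = 0.251 with an estimated correlation). By edgeR 25 genes were higher and 1 lower, against 30 and 5 with DESeq2, 44 and 13 with no expression filter and 16 and 7 with TPM of all genes. The count was 8 without DMSO late G1 replicate 2 and 190 without DMSO S/G2/M replicate 1. Between late and early G1 no gene passed in edgeR (999 at an unadjusted p under 0.05, DESeq2 11, limma-voom 1). Histone genes had a median of -1.20 (20 fell when adjusted over the list alone, camera adjusted p = 1.92e-17, adjusted p = 0.903 with an estimated correlation), which became -0.21 (0.668) with the MT-RNR2 share as a covariate. Mitochondrially encoded genes had a median of 0.88 (3 rose when adjusted over the list alone, camera adjusted p = 1.02e-06, adjusted p = 0.903 with an estimated correlation), which turned to -0.33 (0.621) with that covariate. That count was 6 without either DMSO early G1 library, 7 and 2 without DMSO late G1 replicates 1 and 2, and 75 and 76 without DMSO S/G2/M replicates 1 and 2. Between S/G2/M and early G1 no gene passed either (703 at an unadjusted p under 0.05, DESeq2 5, limma-voom 0). Histone genes had a median of 0.85 (21 rose when adjusted over the list alone, camera adjusted p = 5.55e-15, adjusted p = 0.356 with an estimated correlation), which was 0.26 (0.068) without DMSO S/G2/M replicate 2 and 1.51 with the MT-RNR2 share as a covariate. The count was 7 without either DMSO early G1 library, 5 and 4 without DMSO late G1 replicates 1 and 2, and 28 and 112 without DMSO S/G2/M replicates 1 and 2. In control the same histone median was 1.85. Ribosomal protein genes had medians of -0.18 against late G1 (camera adjusted p = 0.0052, adjusted p = 0.738 with an estimated correlation), which turned to 0.12 with TPM, and -0.20 against early G1 (0.00442, adjusted p = 0.517 with an estimated correlation). The first was lost without DMSO late G1 replicate 2 (0.7) or DMSO S/G2/M replicate 1 (0.645) and the second without the latter (0.54). Without DMSO late G1 replicate 1 the first was -0.27, and without DMSO S/G2/M replicate 2 they were -0.26 and -0.30. Mitochondrially encoded genes fell back from late G1 to S/G2/M as a list (median -0.64, camera adjusted p = 1.61e-05, adjusted p = 0.63 with an estimated correlation), lost without DMSO S/G2/M replicate 2 (-0.31, 0.345) and at -1.22 without DMSO S/G2/M replicate 1. The MT-RNR2 share differed by more between these DMSO groups (47.8, 60.7 and 56.1%) than between the control groups (45.7, 45.2 and 48.0%).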

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

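The tests of the MT-RNR2 share, of GC content and length and of the sorted cells on the histone genes were chosen only after the result was seen. Each result below is a gene list whose DMSO effect differed between phases by camera on the interaction. None of them held with an estimated correlation, where the lowest adjusted p was 0.0651, and no single gene passed an interaction test in edgeR (562, 684 and 502 genes at an unadjusted p under 0.05, and 1, 1 and 2 calls by DESeq2 and 1, 0 and 1 by limma-voom).

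Replication-dependent histone genes package new DNA in S phase, and their DMSO effect was lower in late G1 than in early G1 by a median difference of -0.96 (camera adjusted p = 6.5e-13, 0.744 with an estimated correlation). It was lower in S/G2/M than in early G1 by -1.01 (5.65e-14, 0.274 with an estimated correlation), by -0.62 without DMSO S/G2/M replicate 1 and by -1.53 without replicate 2 of that group. The MT-RNR2 share of the libraries stays open as a technical explanation. In 5 of 6 groups the library of higher share had the lower histone median. With that share as a covariate the late G1 median turned from -0.67 to 0.20 and the difference between late and early G1 became -0.12 (0.846). The library of higher share was replicate 1 in every group, so share and replicate number cannot be told apart here. The share of nuclear ribosomal RNA, looked at after the result was seen, stays open too. Within every group the library of lower such share had the lower histone median, and that share separates the treatments. GC content and length do not account for the whole difference, since the S/G2/M median was -0.562 with offsets for them. A change in the cells sorted cannot be told apart from these shares. Fewer S phase cells in the late G1 gate would lower S phase genes, whose median there was 0.502. Fewer cycling cells in the S/G2/M gate would lower mitotic genes, whose median there was -0.397. The S phase list did not hold with an estimated correlation (adjusted p = 0.128) and the mitotic list lost its call without DMSO S/G2/M replicate 2 (0.139), so neither value decides.

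The DMSO effect on S phase genes was lower in S/G2/M than in late G1 by -0.44 (camera adjusted p = 0.000311, and -0.33 with 0.073 under a stricter filter). Against early G1 it was lower by -0.43 (0.00235, with 0.108 without DMSO S/G2/M replicate 2 and -0.17 with 0.0642 under that filter). G2 and mitosis genes differed by -0.68 between S/G2/M and late G1 (1.02e-06), a call kept with each library left out. Between S/G2/M and early G1 they differed by -0.29 (0.00119), by -0.47 without DMSO S/G2/M replicate 1 and by -0.18 (0.196) without replicate 2. Mitochondrially encoded genes differed by 0.85 between late and early G1 (0.000802), a call lost without control early G1 replicate 2 (0.47, 0.0747), DMSO early G1 replicate 2 (0.55, 0.0913) or DMSO late G1 replicate 1 (0.63, 0.0761), and turned to -0.47 with the MT-RNR2 covariate. They differed by -0.53 between S/G2/M and late G1 (0.0397), a call lost without control late G1 replicate 1 (-0.69, 0.14) or 2 (-0.37, 0.076), control S/G2/M replicate 1 (-0.019, 0.527), DMSO late G1 replicate 1 (-0.32, 0.347) or DMSO S/G2/M replicate 2 (-0.055, 0.735). That difference was -0.85 without control S/G2/M replicate 2, -1.02 without DMSO S/G2/M replicate 1 and 0.15 with the covariate.

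Structural noncoding RNAs differed by -1.49 between late and early G1 (0.0025), a call lost without control early G1 replicate 2 (0.0656), control late G1 replicate 2 (-0.98, 0.117) or DMSO late G1 replicate 1 (0.0761) or 2 (0.059), and with the MT-RNR2 covariate (-0.34, 0.324). They differed by -1.24 between S/G2/M and early G1 (0.000361), by -0.82 without control S/G2/M replicate 2 and by -0.76 without DMSO S/G2/M replicate 1. Matrix genes differed by 0.53 between S/G2/M and late G1 (0.0112), lost without control late G1 replicate 1 (0.104), control S/G2/M replicate 1 (0.0517) or DMSO late G1 replicate 2 (0.129) and with GC and length offsets (0.41, 0.197). Between S/G2/M and early G1 they differed by 0.51 (0.00942), lost without control early G1 replicate 2 (0.19), control S/G2/M replicate 1 (0.32, 0.0753), DMSO early G1 replicate 1 (0.0727) or DMSO S/G2/M replicate 2 (0.14, 0.196) and with GC and length offsets (0.29, 0.238).

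The activin, NODAL and TGF-beta list differed by 0.48 between S/G2/M and early G1 (0.0167), lost without control early G1 replicate 1 (0.0571), control S/G2/M replicate 2 (0.29, 0.0953) or DMSO S/G2/M replicate 1 (0.30, 0.198) and with the MT-RNR2 covariate (0.17, 0.149). In that comparison the phosphoinositide 3-kinase list differed by 0.19 (0.0454). This call was kept in 5 of 29 settings and, among libraries left out, only without control S/G2/M replicate 2 (0.33), with adjusted p from 0.057 to 0.291 otherwise. Its difference was 0.036 without control S/G2/M replicate 1, 0.34 without DMSO early G1 replicate 2 and 0.00022 with GC and length offsets. Ribosomal protein genes differed by -0.29 (0.000361), by -0.15 (0.141) without DMSO S/G2/M replicate 1, by -0.19 without control S/G2/M replicate 2 and by -0.14 with GC and length offsets (0.101) or the MT-RNR2 covariate (0.241).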

How the results depend on the processing

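The offsets for GC content and length, the thinned library, the fits without the 3 libraries of highest MT-RNR2 share or without the shallowest library of each late G1 group, and the MT-RNR2 covariate were chosen after seeing the data. The other alternatives were set before. With 2 libraries per group at the depth and spread seen here, a 2-fold change was recovered in 13 to 22% of simulated genes within a phase and in 69% on average. Genes of low mean count were not among those changed. The cause was not tested for any value below, except that a threshold of 0.01 or of 1 on the log2 scale can only lower a count. With a library left out, the other library of its group is assumed to vary like the other groups.

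Of 339 calls of named genes, 307 were kept with DESeq2, 334 with RLE, 283 with limma-voom, 317 without the low-count filter, 307 with GC and length offsets, 326 with the thinned library, 238 without the shallowest late G1 libraries, 165 with the MT-RNR2 covariate and 257 to 324 with a library left out. Fewest were kept with TPM: 122 of 329 with a pseudocount of 1, 111 of 329 with 0.1 and 71 of 339 with all genes. With the libraries of each group summed, which leaves the spread between phases as error, the averaged comparison called 1838 genes, 1752 of them among the 2301, and kept 105 of 119 calls of named genes. The 14 lost were AKT1, BMPR1A, INSIG1, HDAC9, BAG3, HIST1H3H, HIST1H2BI, KLF6, NGFR, MT-RNR2, MT-RNR1, SESN1, FZD2 and PTPN14. Of 57 calls of lists, 57 were kept with DESeq2, 29 with fry, 42 with GC and length offsets and 2 with an estimated correlation (0 of 24 for DMSO).

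Counts of genes for DMSO against control in early G1 (359), late G1 (719), S/G2/M (428) and averaged (2301) moved as follows. With TPM and a pseudocount of 1 they were 21, 74, 42 and 958, with a pseudocount of 0.1 they were 14, 98, 27 and 850, and with TPM of all genes 66, 31, 50 and 569. At an adjusted p under 0.01 they were 140, 227, 136 and 1251. Without the 3 libraries of highest MT-RNR2 share early G1 had 720, S/G2/M 280 and the average, which then has no late G1, 1144. With the MT-RNR2 covariate they were 545, 31, 196 and 493. Early G1 had 952 in a fit of the compared groups and 594 with GC and length offsets, and S/G2/M had 95 with the compared groups. Late G1 had 97 without the shallowest libraries. The averaged count was 1439 with the stricter filter and 1022 at an absolute log2 fold change of at least 1. With a library left out they ran from 117 to 688, 223 to 1200, 89 to 994 and 1757 to 3122.

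In control, late against early G1 (1 gene) had 2 with limma-voom, 14 without a filter, 0 with either TPM pseudocount, 10 with TPM of all genes, 0 without mitochondrial and structural RNAs, 2 with the replicate block, 5 with the compared groups, 2 with GC and length offsets, 3 without the shallowest libraries, 3 with the MT-RNR2 covariate and 1 to 14 with a library left out. S/G2/M against late G1 (41) had 69 with limma-voom, 67 without a filter, 7, 6 and 8 with the TPM settings, 26 at an adjusted p under 0.01, 62 without the 3 libraries of highest MT-RNR2 share, 26 without the shallowest libraries and 16 to 65 with a library left out. S/G2/M against early G1 (31) had 67 without a filter, 0 with either TPM pseudocount, 52 without the 3 libraries of highest MT-RNR2 share and 19 to 56 with a library left out.

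In DMSO, late against early G1 (0) had 11 with DESeq2, 1 with limma-voom, 70 without a filter, 9 with the 0.1 pseudocount, 27 with TPM of all genes, 5 with the replicate block, 76 with the compared groups, 14 with GC and length offsets, 8 without the shallowest libraries and 0 to 76 with a library left out. S/G2/M against late G1 (26) had 5 with limma-voom, 57 without a filter, 42 with the 0.1 pseudocount, 17 with the compared groups, 12 at an adjusted p under 0.01, 17 without the shallowest libraries and 8 to 190 with a library left out. S/G2/M against early G1 (0) had 5 with DESeq2, 36 without a filter, 32 with TPM of all genes, 1 with the replicate block, 3 with GC and length offsets, 32 without the 3 libraries of highest MT-RNR2 share, 34 with the MT-RNR2 covariate and 0 to 112 with a library left out.

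The interactions (0 genes each by edgeR, with 562, 684 and 502 at an unadjusted p under 0.05) had these counts. Late against early G1 had 1 with DESeq2, 1 with limma-voom, 8 without a filter, 2 with the replicate block, 3 with the compared groups, 2 without the shallowest libraries and 0 to 2 with a library left out. S/G2/M against late G1 had 1 with DESeq2, 8 without a filter, 1 with the compared groups, 2 without the shallowest libraries and 0 to 50 with a library left out. S/G2/M against early G1 had 2 with DESeq2, 1 with limma-voom, 6 without a filter, 30 with TPM of all genes, 1 with the compared groups, 6 without the 3 libraries of highest MT-RNR2 share, 1 without the shallowest libraries, 2 with the MT-RNR2 covariate and 0 to 16 with a library left out.

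The correlation of DMSO effects between early and late G1 (0.507) was 0.152 without a filter, 0.307 with the 0.1 pseudocount, 0.317 with TPM of all genes and 0.312 to 0.435 with a library left out. Between early G1 and S/G2/M (0.486) it was 0.151, 0.297 and 0.309 with these settings, 0.309 without the 3 libraries of highest MT-RNR2 share and 0.311 to 0.430 with a library left out. Between late G1 and S/G2/M (0.452) it was 0.132 without a filter, 0.681 with the stricter filter and 0.251 to 0.432 with a library left out.

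Signs turned mostly with the MT-RNR2 covariate. In late G1 they turned for CHORDC1 (-0.28), TUBB3 (0.21), MT-RNR2 (-0.11) and DTL (-0.23). On average they turned for AKT1 (0.093), MT-RNR2 (-0.092) and RPL18 (0.074). As the covariate is MT-RNR2's own share of counts, the values of MT-RNR2 under it are no test of that gene. Histone lists turned in late G1 (0.20), on average (0.23) and for S/G2/M against late G1 as an interaction (-0.46). Mitochondrially encoded genes turned in late G1 (-0.63), S/G2/M (-0.56), on average (-0.49), for late against early G1 in DMSO (-0.33), for S/G2/M against early G1 in DMSO (-0.69) and for the interactions of late against early G1 (-0.47) and S/G2/M against late G1 (0.15). Ribosomal protein lists turned in late G1 (0.29), on average (0.16) and for S/G2/M against early G1 in DMSO (-0.013). DTL in late G1 also turned with TPM and a pseudocount of 1 (-0.0047) or 0.1 (-0.0091) and with TPM of all genes (-0.0047). TOP2A on average turned without the 3 libraries of highest MT-RNR2 share (-0.47), an average that leaves out late G1. TP53INP1 on average turned without control late G1 replicate 1 (0.27, with -3.52 as the lowest value with a library left out).

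Some scalings moved the median of all genes, to which changes are relative. Without a filter it was -0.16 for the averaged comparison, -0.20 for late against early G1 as an interaction and 0.26 for S/G2/M against late G1. With TPM and a pseudocount of 1 or 0.1 it was -0.29 and -0.36 for late against early G1 in control, 0.12 and 0.16 for S/G2/M against late G1 and -0.16 and -0.19 for S/G2/M against early G1. In DMSO these were -0.33 and -0.43, 0.21 and 0.26, and -0.12 and -0.15. With the 0.1 pseudocount the S/G2/M against late G1 interaction was at 0.12.

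The check of replicate numbers was mixed. The differences between replicates 1 and 2 correlated at -0.22 to 0.42 over 15 pairs of groups, and the 5 below 0 were the pairs with control early G1. The numbers were therefore not taken to pair the libraries. With a block on replicate number the DMSO counts were 419, 912, 459 and 2446. With that block 7 list calls were lost: fibroblast markers in early G1 (camera adjusted p = 0.0534) and S/G2/M (0.0724), immediate early genes in early G1 (0.0534), primed markers in late G1 (0.053), epithelial adhesion genes on average (0.057), structural non-coding RNAs in S/G2/M against early G1 in control (0.0692) and phosphoinositide 3-kinase genes in the S/G2/M against early G1 interaction (0.056).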

Other observations

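The lists of this part, the offsets for GC content and length, the tests of the MT-RNR2 share, the test of other cell types, the fit with the ribosomal RNA share as a covariate, its standard errors and the chromosome value with offsets were chosen only after the result was seen.

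Transfer RNA ligases, which charge transfer RNAs with amino acids, and other targets of the stress factor ATF4 rose with DMSO as a group. Of 19 tested genes in the averaged comparison 12 rose, among them STC2, VLDLR, ALDH1L2, GARS, AARS, IARS, SLC1A5 and NARS, with a median log2 fold change of 0.726 (camera adjusted p over the added lists = 1.98e-06, 0.0249 with an estimated correlation). With GC and length offsets the median was 0.62. Assembly factors of the ribosome rose as well: 11 of 24, including DDX21, WDR12, WDR43, LYAR, NOLC1, GNL3 and NCL, with a median of 0.377 (0.00482, and 0.0547 with an estimated correlation). Lysosomal genes, which break down cell components, were lower, with 7 falls and 1 rise of 22 (CTSB, NEU1, GRN and PSAP among those called) and a median of -0.364 (0.00738, and 0.0449 with an estimated correlation). All 3 tested of 8 transcripts driven by HERV-H repeats, LINC00458, SCGB3A2 and ABHD12B, rose, with a median of 2.53, and such repeats are active in pluripotent cells. Of 6 tested FOXO targets ERBB3 and SESN3 fell, with a median of -0.671 (0.0202, and 0.0547 with an estimated correlation), although FOXO1 itself rose by 1.87. These lists were written and tested on the same libraries, so what they show is a hypothesis. Not each held in single phases. Of the HERV-H transcripts only LINC00458 was called in any phase alone, in late G1. In S/G2/M the lysosomal median was -0.064 (0.165), the FOXO list was at -0.17 (0.326) in late G1 and -0.36 (0.11) in S/G2/M, and the ribosome assembly list was at 0.39 (0.0633) in late G1.

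The genes that differed between DMSO and control on average were weighed against technical explanations. The grouping of these libraries by chance did not account for them, since 1 of 100 splits within phases, the real one, called as many genes (2301, and at most 678 in another split). As the libraries of a group are technical replicates, chance differences between cultures stay open. GC content and length did not account for them: with offsets the slope of the fold changes on those without was 0.949, and 1954 of the 2301 kept their call. Among the 2295 called genes with a GC value, higher genes had a lower median GC content (43.6%) than lower ones (53.3%). The MT-RNR2 share did not account for all of them: its group means were close in early G1 (45.7 and 47.8%), where 95.4% of 917 genes called in a later phase had the same direction. Of all genes, 69.0% had the same direction in early and late G1 and 67.0% in early G1 and S/G2/M. With that share as a covariate 355 of 359 calls in early G1 were kept, but 27 of 719 in late G1 and 399 of the 2301 on average. Over the 2301 the slope on the fold changes without it was 0.854, the median absolute log2 fold change went from 0.932 to 0.685 and the median standard error from 0.229 to 0.358, and 103 genes turned. In late G1 the slope was 0.815, but the shares there separate the treatments, so the part of the share in the late G1 changes stays open. The share of nuclear ribosomal RNA stays open, since slopes on that share within groups went with the DMSO effect (r = -0.401, and -0.228 with GC and length offsets), and every control library held at least 6.67% and every DMSO library at most 4.91%. With it as a covariate 522 genes were called, 395 of them among the 2301. Of the 2301, 143 had the opposite sign, the slope of the fold changes on those without the covariate was 0.837, the median absolute log2 fold change was 0.669, and the median standard error was 0.353. Calls were thus lost to smaller folds and to wider errors, which a covariate that separates the treatments brings, so these losses do not decide.

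The higher pluripotency genes were weighed likewise. Their averaged median was 0.669 with GC and length offsets (camera adjusted p = 2.24e-07) and 0.921 in early G1 alone, where the MT-RNR2 shares were close, so neither accounts for the whole rise. In late G1 the MT-RNR2 covariate took the median from 0.84 to 0.54 and ended the call (camera adjusted p = 0.0708), so part of the rise there may go with that share. Fewer cells of other types in the DMSO cultures would raise all pluripotency genes alike if those cells expressed none of them, which was not measured. They moved apart by more than their errors (Cochran's Q test over 15 genes, n = 12 libraries, Q = 265.7 on 14 degrees of freedom, p = 1.6e-48). For these 15 genes that argues against 1 common factor as the whole of the rise in these libraries. Their errors hold only the spread between technical replicates. Chance differences between cultures, and fewer cells of other types as a part of the rise, therefore stay open. With the ribosomal RNA share as a covariate the median was 0.57 and 7 members were called as higher, but that share separates the treatments and stays open. These libraries hold no test that separates a response of the pluripotency network to DMSO from that share.

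A gain or loss of a whole chromosome between the cultures could not be decided. Over 22 autosomes the largest median of the averaged log2 fold changes was 0.294, on chromosome 13 (186 genes), and it was 0.153 with GC and length offsets.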
